A study of Mus musculus with 12 samples.

How the data were processed

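Hippocampal 5hmC was measured in 3 stress and 3 control DNA pools and RNA in the same pools, all from male C57BL/6 mice. Per the labels, 10 ug of DNA was sonicated to 300 bp, 5hmC was tagged with an azide-modified glucose and biotin, and captured fragments were sequenced as 50 nt single reads. RNA libraries were made from 100 ng of total RNA and sequenced as 100 nt paired reads. Samples were grouped by their titles and treatment tags.

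For each 5hmC library the authors deposited 1 list of peaks with a score per peak. The peak names in the deposited lists are those MACS gives, and its version is not given in the sources used here. Reads were aligned to mm9 with Bowtie 0.12.9, per the submitters' processing notes, which also name edgeR. Whether an input library was used is not given in the sources used here. The lowest deposited score was 50 in all 6 lists. Scores were used only to rank peaks within a list and never compared between lists, and lists were compared by overlap. For RNA, the authors deposited 1 table per group in Cufflinks format, with FPKM and an interval for each of 33262 RefSeq transcripts. TopHat 1.0.12, Cufflinks 2.1.1 and Cuffdiff 2.1.1 were used, per the submitters' processing notes. No counts are in the tables. Coverage per FPKM, which follows sequencing depth, was 8.14 in the control and 9.22 in the stress table.

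Peaks on chromosomes 1 to 19, X and Y were used, and those on other sequences (1 to 4 per library) were left out. Peaks of the 6 lists that overlapped by at least 1 bp were merged into regions without bridging gaps. A library had a region when any of its peaks overlapped it. Gene bodies, exons and start sites came from the RefSeq transcripts in the RNA tables, which use mm9, so no coordinates of the GRCm38.p6 reference were used. That reference served only to match older gene symbols. Peak-covered bases were assigned to promoter (within 1 kb of a start site), exon, intron or intergenic, in that order. Coverage of a gene is the percentage of its body under peaks. The median over list members, which had been planned, was 0 in most libraries, so the mean was used and divided by the mean over all genes of at least 10 kb.

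FPKM of isoforms were summed per gene. Differences are log2((stress + 1)/(control + 1)), with a pseudocount of 1, which understates the change of low genes. Genes with a mean of at least 1 FPKM were kept, 11071 of 23953. The deposited FPKM lay outside the deposited interval for at least 1 transcript in 2683 of these genes, so the intervals were not used as errors. A gene at exactly 0 is described as listed at 0, without a fold. Genes at several loci and close paralogs can share reads, and their values are uncertain.

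Groups of libraries were compared with exact two-sided permutation tests over all 20 assignments of 6 libraries to 3 and 3, whose smallest p is 0.1. Benjamini-Hochberg adjustment was made within each family of tests. Regions found in 1 group only were counted for all 10 ways of parting the libraries into 3 and 3. Members of 14 gene lists and 16 marker lists with such regions were compared with 10000 random lists matched on gene length (one-sided permutation test). RNA medians of lists were placed among 10000 random lists of the same size matched on mean FPKM, as a description without a test. Percentiles of the latter refer to the 2 tables alone.

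The lists, the tests of the report and the rule for naming genes were chosen before the data were examined, and some tests of technical explanations afterwards. The rule named the 15 highest and 15 lowest RNA differences, the 10 genes with most stress-only and with most control-only regions, the 2 highest and 2 lowest members of each list and members with such a region, and 11 fixed genes (Nr3c1, Fkbp5, Sgk1, Fos, Arc, Bdnf, Tet1, Tet2, Tet3, Dnmt1, Dnmt3a). The text names a part of the genes under this rule. Most of the 15 highest and lowest were listed at 0 in 1 table or short RNAs. For that reason Tsc22d3, Ddit4, Nfkbia, Cdkn1a, Errfi1, Folr1 and Foxj1 were named after their values were seen.

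Alternatives chosen in advance were the same number of top-scoring peaks per library, the higher-scoring 50% of each list, a region counted only for libraries covering at least 50% of it, gaps up to 200 bp bridged, autosomes only, promoters of 2.5 kb, all genes as reference, gene bodies extended by 5 kb, leaving out each library, and replicate numbers as blocks. For RNA they were a pseudocount of 0.1, no filter on low values, centring on the median of all genes and the most abundant isoform. Added after seeing the data were the same covered length per library, annotation shares for the higher-scoring 50% of each list, peaks replaced by 500 bp around their centre, length-weighted list coverage, and only genes above 0 in both tables with a transcript of at least 300 nt.

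The steps were tested on simulated data. All 200 of 200 stress-only regions planted in the real lists were recovered. They lay away from every real peak, with overlapping copies in all 3 stress lists, so their recovery was certain if the code ran correctly. Missed peaks and control peaks nearby were not simulated. Of 100 lists of 25 genes shifted by 0.3 on the log2 scale among the 11071 genes, 100 lay above the 97.5th percentile. Smaller shifts were not tried. Of the 100 unshifted lists, 2 lay outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.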

Results

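The hippocampus of male C57BL/6 mice was profiled after a single episode of restraint, to ask which genes carry an altered 5-hydroxymethylcytosine (5hmC) profile soon after acute stress. 5hmC is an oxidised form of methylated cytosine that is abundant in neurons and is made by the TET enzymes. Stressed mice (6 animals) were restrained for 30 min and left for 1 h before tissue collection, and control mice (5 animals) were not restrained. DNA pools of at most 2 mice gave 3 stress and 3 control 5hmC libraries, each with its own list of peaks. RNA from the same pools was summarised in 1 table of transcript levels per group, in FPKM (fragments per kilobase of transcript, scaled to the total of the table). The sample tags give an age of postnatal day 28 and the protocol gives 7 weeks. A time of 2 h after lights on is given for the stress group and none for the control group. Whether time of day differed between the groups could therefore not be examined, for RNA or for 5hmC.

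The peak lists held 15195, 27797 and 31654 peaks in stress replicates 1, 2 and 3. Control replicates 1, 2 and 3 held 17186, 27916 and 16327 peaks. Peaks covered 29.4 ± 11.3 Mb of the genome in stress libraries and 21.2 ± 7.69 Mb in control libraries (SD, n = 3 each). Neither the number of peaks (24882 ± 8608 against 20476 ± 6457; exact two-sided permutation p = 0.7) nor the covered length (p = 0.4, same exact permutation test) differed beyond the spread between libraries. The median peak length was 1028 ± 45.7 bp in stress and 932 ± 34.6 bp in control libraries, with no overlap between the groups (exact permutation p = 0.1, n = 3 each). That is the smallest p that 3 against 3 libraries allow, so none of these exact tests between the groups of libraries could pass 0.05, and their p-values measure the spread between pools of mice. The labels give about 25000000 to 35000000 uniquely mapped reads per library, and the depth of each single library is not given in the sources used here.

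**Figure D1:**
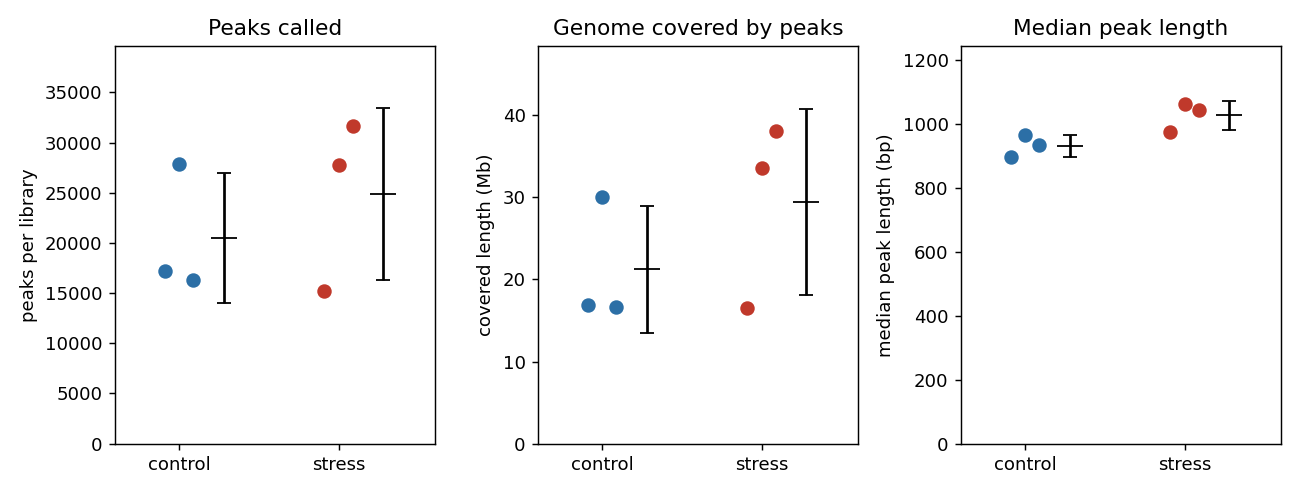
Number of peaks, covered length in Mb and median peak length in bp for each 5hmC library (points), with the mean and SD of 3 libraries per group (bars). The 3 stress lists have longer peaks than the 3 control lists, while numbers of peaks and covered lengths overlap between the groups.

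The first comparison asked where 5hmC peaks were called after stress and not in controls, and the reverse. A region counted as stress-only when all 3 stress libraries and no control library had a peak there. A library without a listed peak, where the lowest score was 50, may still hold 5hmC there. There were 847 stress-only regions, of which 567 lay in the bodies of 583 genes, some of them overlapping. Of 276 control-only regions, 157 lay in the bodies of 156 genes, and 14 genes were in both sets. Dnmt3a, which encodes the enzyme that places new DNA methylation, held 1 stress-only region, and Dnmt3b, which encodes the other such enzyme, held 1 control-only region. Length-matched random lists of the size of their list, the DNA methylation and 5hmC machinery, held 0.695 and 0.16 such genes on average. The one-sided permutation p was 0.502 for stress-only and 0.149 for control-only regions. Peaks covered 7.54% ± 3.32 of the body of Dnmt3a in stress libraries and 2.22% ± 0.555 in control libraries (SD, n = 3 each). This coverage includes the stress-only region, so it is no separate support for it. The exact permutation p was 0.1, and 0.55 after adjustment over the 11 fixed genes. Crebbp, a histone acetyltransferase and partner of the activity-regulated factor CREB, held 2 stress-only regions.

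Akap6, a scaffold that anchors protein kinase A at the nuclear envelope, held the most stress-only regions, with 3 on chromosome 12 between 53819418 and 54243756 (mm9). Another 16 genes held 2 each, and those with the longest regions were Ece1 (endothelin processing), Macrod1 (removal of ADP-ribose), Arfgap3 and Asap1 (membrane traffic through ARF), Wwox (a tumour suppressor oxidoreductase), Trak1 (transport of mitochondria along axons), Tnpo1 (nuclear import), Gtpbp1 (a GTP-binding protein) and Crebbp. Among control-only regions, Pde4d, which breaks down cAMP, and Focad, a focal adhesion protein, held 2 each. The next genes, each with 1, included Daam1 (actin assembly), Dym (Golgi organisation), Asap1, Hs2st1 (heparan sulphate synthesis), Adcy6 (cAMP synthesis), Uck2 (uridine salvage) and Tmem108 (spine development). Long genes hold more regions by chance, and these counts per gene were not tested against gene length. The body of Akap6 spans 452 kb. The other stress-only genes named here span 30.6 kb (Gtpbp1) to 913 kb (Wwox), and the control-only genes 17.6 kb (Adcy6) to 1302 kb (Pde4d).

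The excess of stress-only over control-only regions varied with the way of counting and with the libraries used. The ratio of stress-only to control-only regions was 3.07 with all peaks. It was 1.71 (531 against 310) with the same number of top-scoring peaks from every library, and 1.06 (389 against 366) with every list shortened by score to the same covered length. It stayed at 3.01 with the higher-scoring 50% of each list, 3.33 when libraries had to cover at least 50% of a region, 3.12 with gaps bridged and 3.07 on autosomes only. Leaving out stress replicate 1, 2 or 3 gave ratios of 10.3, 3.87 and 2.98, and leaving out control replicate 1, 2 or 3 gave 0.919, 2.14 and 0.928. With a library left out, a region needs a peak in only 2 libraries of that group. For the other group, only the same 2 must be without a peak. Both counts rose, and the 2 groups no longer met the same rule. The ratio can shift for that reason alone. Of all 74450 regions, 42395 had a peak in a single library and 1211 in all 6. With all peaks, the grouping of stress 2, stress 3 and control 2, the lists with the most peaks, against the rest gave 1737 regions, more than the 1123 of the study's groups. The mean Jaccard index, the share of covered bases held in common, was 0.179 within groups and 0.161 between groups. Of 10 groupings of the libraries, 2 gave a difference at least as large as this 0.0178. Pairs of stress libraries had 0.180, 0.174 and 0.254, and pairs of control libraries 0.149, 0.150 and 0.165. All but the 0.254, of stress replicates 2 and 3, lay within the range of pairs between groups (0.130 to 0.222). Control libraries thus shared no more with each other than pairs between groups did. With the same number of peaks per library the difference was 0.0222, the largest of the 10 groupings. Control pairs then had 0.147, 0.149 and 0.165, beside a mean of 0.156 between groups.

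**Figure D2:**
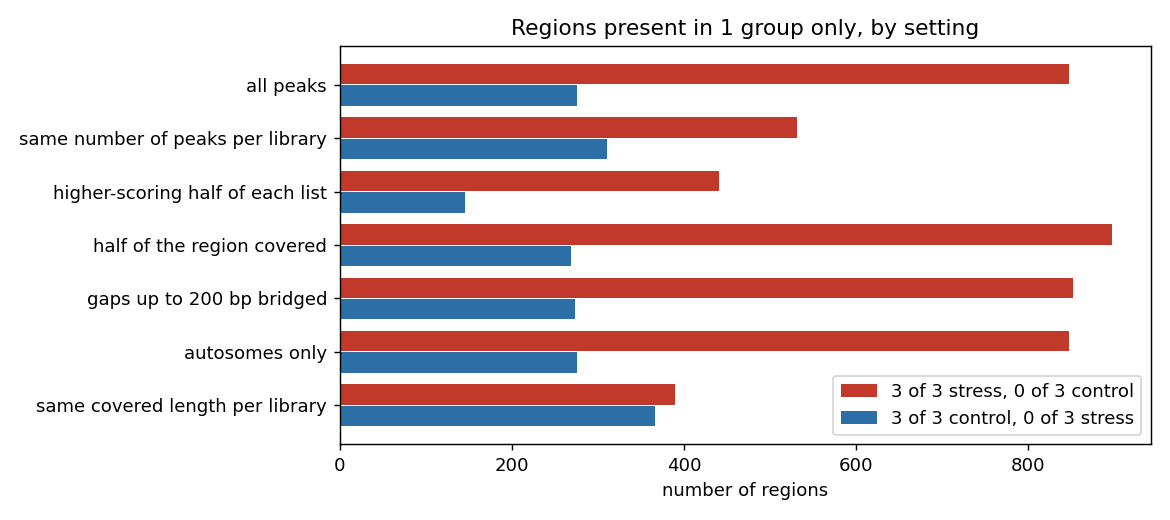
Number of regions with a peak in all 3 libraries of 1 group and none of the other (bars), with all peaks and under each alternative way of counting. The stress-only excess with all peaks (847 against 276) shrinks to 389 against 366 when every list covers the same length.

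The next comparison asked in which parts of genes the peaks lay. Exons took a larger share of peak-covered length in every stress library (9.13% ± 0.341, SD, n = 3) than in any control library (6.73% ± 0.658, n = 3; exact permutation p = 0.1, Benjamini-Hochberg adjusted over 4 classes 0.133). Promoters, within 1 kb of a start site, took 2.85% ± 0.0934 in stress and 2.41% ± 0.202 in control libraries (exact permutation p = 0.1, adjusted 0.133). Intergenic sequence took 35.6% ± 0.45 and 37.4% ± 0.672 (exact permutation p = 0.1, adjusted 0.133), and introns 52.4% ± 0.26 and 53.5% ± 0.896 (exact permutation p = 0.2, adjusted 0.2). Exons make up 2.15% and promoters 1.87% of the same chromosomes, so both classes held more 5hmC peaks than their length in both groups. The difference in exon share was 2.94 percentage points with the same number of peaks from every library, and stayed between 2.18 and 2.78 when any single library was left out. Among stress-only regions 263 of 847 (31.1%) lay on exons, against 39 of 276 control-only regions (14.1%) and 18.2% of all regions. A region with any base on an exon and none in a promoter counted here, which favours longer regions, and the median length was 1335 bp for stress-only and 1092 bp for control-only regions.

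**Figure D3:**
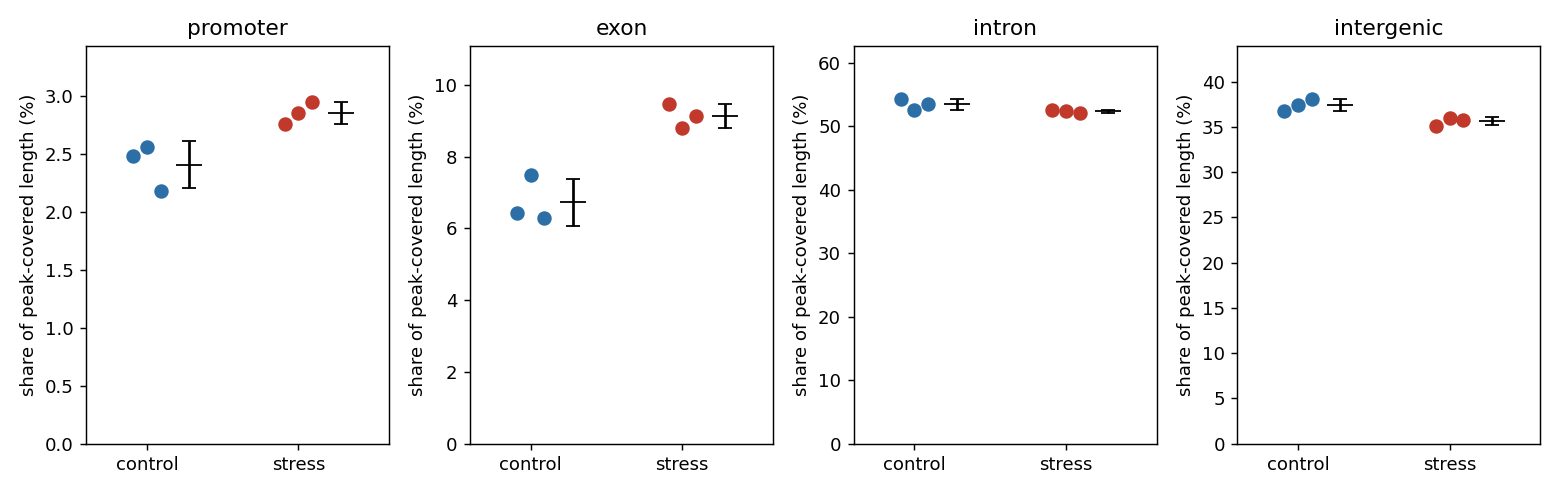
Share of peak-covered length in promoters, exons, introns and intergenic sequence, in percent, for each 5hmC library (points) with the mean and SD of 3 libraries per group (bars). The lowest exon share among stress libraries is 8.79% and the highest among control libraries is 7.48%.

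Genes of the hippocampus that were expressed carried more 5hmC than silent ones in every library. In stress libraries, peaks covered 1.19% ± 0.472 of the bodies of 3295 genes below 0.1 FPKM and 2.94% ± 1.09 of 2233 genes at 10 to below 100 FPKM (SD, n = 3). In control libraries the same classes had 0.719% ± 0.327 and 2.03% ± 0.726. The ratio between these classes was 2.48 ± 0.0834 in stress and 2.90 ± 0.248 in control libraries, without overlap (exact permutation p = 0.1, n = 3 each). Expression was taken from the control table for both groups, for genes of at least 10 kb.

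**Figure D4:**
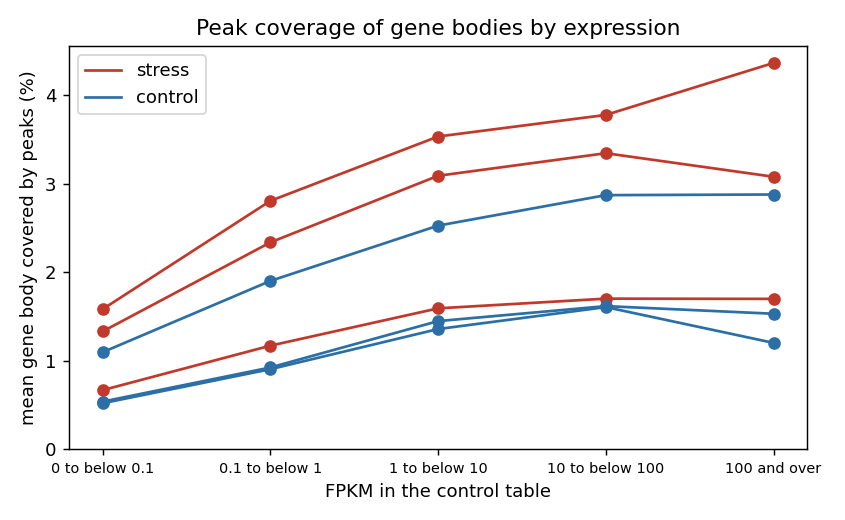
Mean percentage of the gene body covered by peaks, by FPKM class in the control RNA table, with 1 line per 5hmC library. Coverage rises from the lowest class to that of 10 to below 100 FPKM in all 6 libraries, and the class of 100 FPKM and over holds only 74 genes.

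The design also asked whether 5hmC differed over groups of genes tied to stress and plasticity. Of the histone-modifying enzymes, the acetyltransferases Crebbp and Kat2a, the deacetylase Hdac4 and the methyltransferase Kmt2c held stress-only regions, 4 genes where length-matched random lists held 1.37 on average (one-sided permutation p = 0.0444). The demethylase Kdm2b of the same list held a control-only region, where random lists held 0.439 on average (permutation p = 0.362). Plekhg1 and Tcf7l2, a pair of markers of thalamus and neighbouring tissue, held control-only regions (permutation p = 0.0195). None of the 60 tests over all lists and both directions passed Benjamini-Hochberg adjustment (smallest adjusted p 1), and 2 of them had an unadjusted p under 0.05. Mean coverage of gene bodies, relative to all genes of at least 10 kb, was higher in stress in 22 of 30 lists, and none passed adjustment (smallest adjusted exact permutation p 0.833, n = 3 each). The smallest exact permutation p of 0.1 was reached by 2 lists, axon guidance and cell adhesion genes (0.557 ± 0.0455 in stress, 0.733 ± 0.0387 in control) and microglial markers (0.888 ± 0.305 and 0.372 ± 0.169; n = 3 each).

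Genes named in advance for their part in stress or DNA methylation had mixed coverage. Peaks covered 4.04% ± 2.18 of Tet2, an enzyme that makes 5hmC, in stress libraries and 0.922% ± 0.804 in control libraries (SD, n = 3 each). Nr3c1, the glucocorticoid receptor, had 2.08% ± 1.28 and 1.57% ± 0.288, and Fkbp5, which restrains that receptor, had 5.83% ± 3.97 and 2.87% ± 0.412. Sgk1, a kinase induced by glucocorticoids, had 4.40% ± 1.86 and 3.84% ± 1.62. None of the 11 genes passed adjustment, and 3 against 3 libraries could not. The smallest exact permutation p was 0.1 (adjusted 0.55), for Tet2 and Dnmt3a. These percentages are not divided by the coverage of the whole list, which averaged 29.4 Mb in stress and 21.2 Mb in control libraries. Apart from Dnmt3a, none of the 11 held a region found in 1 group only. Tet1, Tet2, Tet3, Dnmt1, Bdnf, Fos and Arc each had at least 1 library without a peak in the gene, and 5 of the 6 regions in Tet2 had a peak in a single library.

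The RNA comparison asked which transcripts differed 1 h after restraint. Genes known to answer glucocorticoids and neuronal activity were higher in the stress table. Sgk1 was at 7.34 FPKM in the control and 21.9 in the stress table, Fkbp5 at 5.55 and 10.2, Tsc22d3 (a glucocorticoid-induced transcription regulator) at 7.42 and 15.2, and Ddit4 (an inhibitor of mTOR) at 17.4 and 34.2. The cell cycle inhibitor Cdkn1a was at 1.07 and 3.19, the sulphotransferase Sult1a1 at 0.482 and 2.16, the NF-kappaB inhibitor Nfkbia at 2.48 and 5.72, and Errfi1, which inhibits EGF receptors, at 4.05 and 8.85. Among genes induced by activity, Fos was at 0.60 and 3.34 FPKM, Arc (a synaptic plasticity protein) at 10.4 and 21.4, and Gadd45b (a DNA demethylation factor) at 0.978 and 3.36. Bdnf (a neurotrophin) was at 9.07 and 9.06, and Nr3c1 was at 8.58 and 7.17. With 1 table per group there was no replicate and no test, so these values describe the 2 tables and not the conditions.

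All 27 glucocorticoid-induced genes with a mean of at least 1 FPKM lay above the median of all genes, which was 0.08 on the log2((stress + 1)/(control + 1)) scale used for every log2 difference given here. Their median log2 difference was 0.63, above all of 10000 random lists matched on mean FPKM (central 95% of medians 0.01 to 0.15). Immediate early genes had a median of 0.37 (28 genes, 20 above the median of all genes), also above all random lists. Heat shock and unfolded protein response genes had a median of 0.18 (percentile 99.8, but 95.6 for the most abundant isoform only), led by Herpud1 (degradation of misfolded proteins, 5.66 and 8.84 FPKM) and the chaperone Hspa1b (3.15 and 5.03). Histone-modifying enzymes had a median of 0.17 (percentile 98.9), led by the demethylase Kdm6b (2.65 and 3.88). The DNA methylation and 5hmC machinery had a median of 0.10 (percentile 66.3). In it Gadd45b and Gadd45g (4.88 and 9.06 FPKM) were highest, while Tet1, Tet2, Tet3, Dnmt1 and Dnmt3a lay between -0.05 and 0.22.

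**Figure D5:**
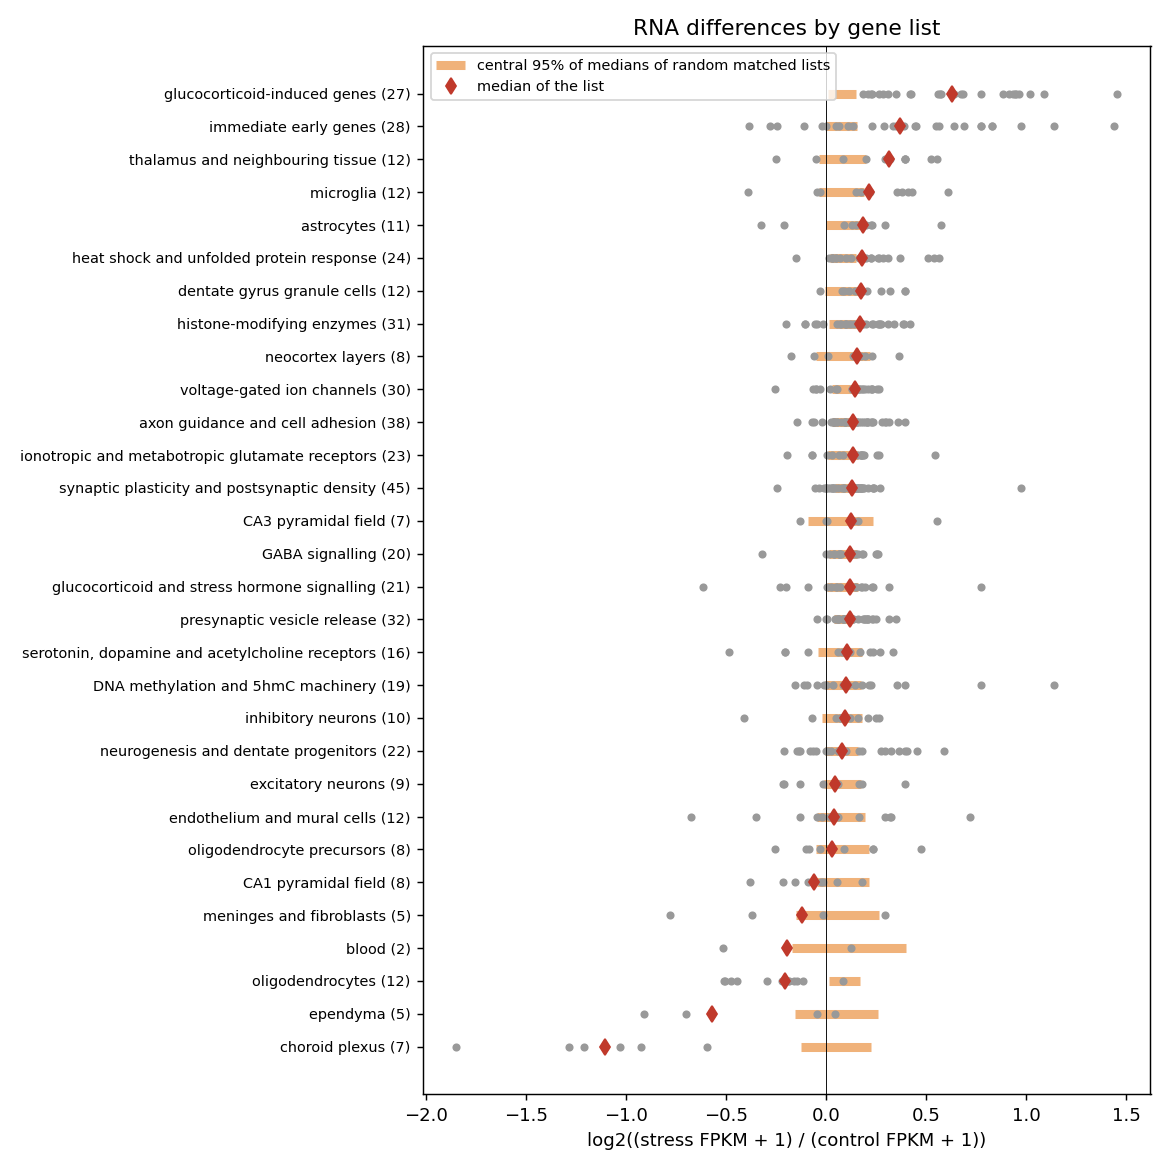
Log2 difference in RNA, stress over control table, for members of each gene list (grey points), the median of the list (red diamonds) and the central 95% of medians of 10000 random lists matched on mean FPKM (orange lines), with the number of genes in parentheses. Glucocorticoid-induced genes stand at the top with 0.63 and choroid plexus markers at the bottom with -1.10.

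Markers of several cell types and tissues differed between the tables beside these gene groups. All 7 choroid plexus markers with a mean of at least 1 FPKM were lower in the stress table, with a median log2 difference of -1.10. Ttr, the thyroid hormone carrier of that tissue, was at 217 FPKM in the control and 59.5 in the stress table, and Folr1, a folate receptor, at 2.21 and 0.389. Ependyma markers had a median of -0.57 (5 genes), and oligodendrocyte markers -0.20, with 11 of 12 below the median of all genes. The myelin genes Opalin (13.9 and 9.46 FPKM) and Mag (20.9 and 14.4) were the lowest of these. Markers of the CA1 field had a median of -0.06 at percentile 1.87, or 3.56 for the most abundant isoform only. Blood markers had -0.19 at percentile 2.14, from only 2 genes, and 0.03 at percentile 75.5 without the filter on low values. Markers of thalamus and neighbouring tissue had a median of 0.32 (above all random lists), those of microglia 0.22 (percentile 99.3) and those of astrocytes 0.19 (percentile 98.6, but 89.3 for the most abundant isoform only).

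Of the other lists, none lay outside the central 95% of random lists with the main settings. Synaptic plasticity genes had a median of 0.13 at percentile 97.0, which became 98.1 with a pseudocount of 0.1 and 98.6 for the most abundant isoform only. The remaining medians were 0.14 for voltage-gated channels, 0.14 for axon guidance and adhesion, 0.14 for glutamate receptors, 0.12 for GABA signalling, 0.12 for presynaptic release, 0.12 for stress hormone signalling, 0.10 for monoamine and acetylcholine receptors and 0.08 for neurogenesis. Among markers they were 0.17 for dentate granule cells, 0.15 for neocortex layers, 0.12 for the CA3 field, 0.10 for inhibitory neurons, 0.05 for excitatory neurons, 0.04 for endothelium and mural cells, 0.03 for oligodendrocyte precursors and -0.12 for meninges and fibroblasts.

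Among 11071 genes with a mean of at least 1 FPKM, 34 were at least 2-fold higher and 32 at least 2-fold lower in the stress table on this scale. These counts were 65 and 63 with a pseudocount of 0.1, and 129 and 99 for the most abundant isoform only. Many of these were genes listed at 0 in 1 table or very short transcripts. Ptprs (a receptor phosphatase), Scn3b (a sodium channel subunit) and Gnl3l (a nucleolar GTPase) were listed at 0 in the control table, with 39.5, 26.9 and 25.4 FPKM in the stress table. Spin1 (a histone reader), Dnajb6 (a chaperone), Ahcyl2 (a regulator of ion transport), Pak3 (a kinase of dendritic spines), Tiam1 (a Rac activator), Acsl4 (a fatty acid ligase) and Hnrnpr (an RNA-binding protein) were listed at 0 in the stress table, with 46.5, 37.8, 37.1, 15.4, 14.2, 12.9 and 7.79 FPKM in the control table. The other 12 of the 15 largest positive differences, and 6 of the 15 largest negative ones, were microRNA, small nucleolar or small Cajal body RNA genes, whose transcripts of under 300 nt a fragment library samples poorly. Amd1 (polyamine synthesis) was at 4.83 and 0.00441 FPKM. Leaving out genes at 0 in a table and genes with only such short transcripts, a choice made after the values were seen, left 13 higher and 18 lower among 11028 genes. Of these 13, 5 were immediate early or glucocorticoid-induced genes, and of the 18, 5 were choroid plexus markers.

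The last comparison joined both assays and asked whether genes with a region found in 1 group only differed in RNA. The 432 such genes with stress-only regions and enough RNA had a median log2 difference of 0.09, at percentile 81.3 of random gene sets matched on mean FPKM. The 127 genes with control-only regions had 0.11, at percentile 83.9. Only 2 of these genes differed at least 2-fold, Scn3b and Dnajb6, both listed at 0 in 1 table.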

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

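Chosen after the data were seen were the same covered length per library, the 500 bp around peak centres, length-weighted list coverage, annotation shares for the higher-scoring 50% of each list, and the restriction to genes above 0 in both tables with a transcript of at least 300 nt. The 847 stress-only regions became 531 with the same number of peaks per library, 389 with the same covered length and 440 with the higher-scoring 50% of each list. That last setting gave 146 control-only regions, against 276. Leaving out 1 library gave from 1080 to 3735 stress-only and from 364 to 1175 control-only regions, since fewer libraries had to meet the rule. Bridged gaps, stricter coverage of the region and autosomes only kept both counts within 1.5 times. Genes at least 2-fold higher and lower in the stress table numbered 65 and 63 with a pseudocount of 0.1, 129 and 99 for the most abundant isoform, and 13 and 18 under the restriction to genes above 0, which tests fewer genes. Median RNA differences of genes with stress-only and control-only regions became 0.056 and 0.061 without a filter, and 0.011 and 0.023 after centring on the median of all genes. For the other changes the cause was not tested. Numbers of peaks, covered length and overlap within groups kept their direction under every alternative run for them. So did exon, promoter, intron and intergenic shares and the expression ratio. None of these passed 0.05 under any, but none could, since the smallest p or share is 0.1, or 0.25 with blocks. Exon shares differed by 1.93 to 3.23 points. The number of gene lists past adjustment stayed at 0, which for coverage was fixed in advance by the same limit. Of 12 lists outside the central 95% of random lists in RNA, 8 stayed outside on the same side in all settings. Heat shock (percentile 95.6), astrocyte (89.3) and CA1 (3.56) lists came inside it for the most abundant isoform, and blood (75.5) without a filter, while synaptic plasticity rose above it with a pseudocount of 0.1 (98.1) and for the most abundant isoform (98.6). Centring shifted all RNA differences by 0.08 and took the medians of immediate early and glucocorticoid-induced genes to 0.29 and 0.55. Replicate numbers as blocks gave the same exon difference of 2.40 points (exact sign-flip permutation p 0.25, the smallest it allows) and could change no call. Blocks leave the differences themselves as they are. These were 4406 peaks, 8.20 Mb of covered length and -0.418 for the expression ratio. Promoter, intron and intergenic shares differed by 0.447, -1.11 and -1.74 points. Same-numbered libraries correlated by 0.0124, 0.00261 and 0.0123, too weakly to treat numbers as pairs, although each library correlated best with its own number. By Jaccard index the numbers did not match: stress replicates 1, 2 and 3 all shared most with control replicate 2 (0.168, 0.221 and 0.222). Depth limits the RNA values in ways the tables do not show, since they hold no counts.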

Other observations

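RNA of glucocorticoid target genes such as Sgk1 and Fkbp5 was higher in the stress table, and at the same time the markers of choroid plexus, the secretory tissue of the ventricles, were lower. On the 5hmC side, more regions were found in all stress libraries and no control library than the reverse. Both patterns, and the genes with the largest RNA differences, were weighed against technical explanations.

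Chosen only after the results were seen were the bounds for the test with the same number of peaks and for the groupings of libraries (both planned as counts), the ratios of other groupings, the use of the higher-scoring 50% as a test of weak peaks, the choroid plexus test and the test of unstable estimates. The same covered length was added once the data had been seen, with its bound set before it was run. The 847 stress-only against 276 control-only regions were weighed first. Whether an unequal number of peaks accounts for the excess could not be decided. The ratio was 1.71 with the same number of top-scoring peaks per library, but other groupings of the 6 libraries then gave 1.09 to 2.39, the larger count over the smaller. With all peaks, 3 of 10 groupings gave a ratio at least as large as the real 3.07, the real one included. The ratio was 0.919 and 0.928 without control replicate 1 or 3, but control-only regions then needed a peak in only 2 libraries. Their number rose from 276 to 1175 and 1174, and stress-only regions from 847 to 1080 and 1089, so these ratios decide little. The stress-only regions were not drawn mainly from the lowest-scoring peaks of their lists, but whether weak peaks feed the excess could not be decided. With only the higher-scoring 50% of each list the ratio was 3.01, or 0.982 times that with all peaks, while the ratios of other groupings changed by 0.942 to 1.12 times. When the peaks in stress-only regions were given the lowest scores of their lists, as a trial of this test, 226 stress-only and 141 control-only regions were left instead of 440 and 146. With the higher-scoring 50%, leaving out control replicate 1 or 3 gave 0.861 and 0.870, close to the values with all peaks and under the same changed rule. The median score percentile of stress-only regions within the list was 60.0. As a test of the cause this decides little too, since the bound of 25 set beforehand was also out of reach. Sets of regions shared by any other 3 lists lay at 49.7 to 58.8, with control-only regions at 56.5. Unequal covered length remains a candidate explanation for the excess: with the same covered length per library the ratio was 1.06, where other groupings gave 1.03 to 1.49. That setting also changed the number of peaks and the lowest score kept in each list. The median length over all peaks was larger in stress lists, so equal numbers of peaks need not cover equal lengths of sequence. Whether longer peaks reflect depth, capture or 5hmC itself was not tested, and stress as a biological cause remains open. RNA markers of several tissues differed between the tables from the same pools. Unequal tissue in the pools was not tested for the 5hmC results either.

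Of the 10 groupings of the 6 libraries, 2 gave at least as many regions found in 1 group only as the real one with all peaks, 1123 in the real grouping and 1737 in the highest other. That other grouping parts the lists with many peaks from those with few. With the same number of peaks, 1 of 10 did, the real one, with 841 regions against 672 in the highest other. That was the same other grouping, and it was again the highest other at the same covered length, with 599 regions against 755 in the real one. The real grouping thus ranked first when the number of peaks or the covered length was made equal. Whether this rank differs from chance was left undecided, and no source for it was tested. With 10 groupings no share under 0.05 can be reached.

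Lower choroid plexus RNA may reflect less of that tissue in the stress pools. All 7 markers with enough RNA were lower, with a median log2 ratio of -1.86 without a pseudocount, from -0.96 for Sostdc1 to -2.51 for Folr1, while Ttr was the most abundant. The punches could also have held less ventricular lining of every kind, since ependyma markers had a median of -0.73. These did not move together, however: Ccdc153, Mia and Foxj1 were lower, and Pltp and Rarres2, which other cells may express too, were at 0.05 and -0.07. A response of the choroid plexus to stress was not tested and remains open, as 1 pooled table per group cannot part it from dissection. Dissection was not tested for the markers of thalamus and of oligodendrocytes, whose medians with the pseudocount of 1 were 0.32 and -0.20.

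Whether the largest RNA differences, in genes with little in common, come from estimates that failed in 1 table was left undecided. Of the 34 genes that differed at least 4-fold, 97.1% were listed at 0 in 1 table or had only transcripts under 300 nt. A value of 0 makes a large difference by itself, as 31 of the 32 genes listed at 0 in 1 table differed at least 4-fold, so this share does not tell a failed estimate from RNA that was absent. Only Amd1 met neither condition, and it was at 0.00441 FPKM in the stress table.

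The X chromosome carried between 4 and 12 peaks per library, 0.26% to 1.07% of the median density of the autosomes. Chromosome 11 had the highest mean density of the autosomes and chromosome 3 the lowest.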
